A study of Mus musculus with 50 samples.

How the data were processed

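Per the submitters' processing notes, reads were demultiplexed with bcl2fastq, trimmed with cutadapt and aligned to mm10 with STAR 2.4.2a, and genes were counted with HTSeq and compared with DESeq2. The starting point here was the deposited tables of counts, 1 for the 24 libraries of ILC3 and DC, 1 for the 6 libraries of Aire WT and KO cells and 1 for the 20 OTII libraries. Counts were whole numbers in the authors' deposited columns and were used as counts. Fold changes in the deposited comparison columns are log2 values per the file headers, and their p-values and adjusted p-values were read as such per the file headers. The authors' deposited comparisons were used only for the numbers of genes they call, and their fold changes have the opposite sign for the 4 stimulations, for MHCII+ ILC3 against ILC3, for the KO comparisons of OTII cells and for Rorc-GFP+ against proliferating cells. The 100 further per-sample columns of normalized and rlog values were not analysed here.

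The 50 samples formed 16 groups and 18 comparisons. The count tables listed 12950, 11322 and 10704 genes, and every listed gene had at least 6 counts in its highest library, so genes under that level were absent from the start. After edgeR's low-count filter by group, 10568, 8540 and 8739 genes were tested. Genes that each table normalizes apart are not comparable in CPM across tables.

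The main test was edgeR's quasi-likelihood F test with robust dispersion, on counts normalized by TMM, with 1 model per table and groups as factors. Differences between responses were tested as contrasts of contrasts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison. The standard error of a log2 fold change was taken from the F value with 1 degree of freedom. The common biological coefficient of variation was 0.17 for ILC3 and DC, 0.27 for Aire WT and KO cells and 0.22 for OTII cells. Values are given as mean ± SD of CPM. The comparisons, gene lists, tests, thresholds and the first set of alternatives were chosen before the data were examined.

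The 38 lists of genes were tested with limma's camera at a preset correlation between genes of 0.01 and again with a correlation estimated from the libraries, in lists with at least 3 tested members, adjusted over the lists of a comparison. The list of mitochondrially encoded genes had 0 genes in the tables. Counts of genes adjusted over the list alone used Benjamini-Hochberg within that list. A gene with no count in a group was given as a bound, with a floor of 3 counts over that group. The summed markers of Rorc-GFP+ cells were compared by an exact permutation test over all splits. With 3 against 3 libraries the smallest exact p is 0.1, and the libraries of 2 groups fail to overlap in 10% of genes by chance.

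Genes named in the text followed a rule. Named were a few fixed genes per table, up to 6 genes per direction with the largest change among those with no overlap between groups and a log2 CPM of at least 4 in the higher group, and up to 4 genes per list with the smallest p. Predicted genes and immunoglobulin and T cell receptor segments were left out, and genes with 1 to 3 counts over a compared group were left unnamed.

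Alternatives were DESeq2 size factors within edgeR, the DESeq2 Wald test with its own size factors and filtering of genes, no low-count filter, the replicate number as a block, each library left out, and a fit of only the groups compared. Where libraries were left out, blocked or thinned, filter and normalization were repeated, so the genes tested changed too. An alternative count was held to be moved when it lay more than 1.5 times from the main count. Chosen after seeing the data were an offset for transcript GC content, leaving out both shallow Aire-GFP+ ILC3 libraries, thinning of Rorc-GFP+ libraries, and list tests without KO replicate 1 of the Aire and of the Rorc-GFP+ set. The GC offset was a loess curve per library with a span of 0.5, on log2 CPM with a prior count of 2, and correlations with GC used genes with a mean log2 CPM of at least 5. Transcript GC and coordinates came from GENCODE M21. Outliers were tested in 45 reported values of groups with 4 libraries. Markers of Aire-GFP+ ILC3 had a log2 fold of at least 5 and 16 CPM. Splits of differences numbered 40 per kind of shuffle, the real one included.

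Spread between replicates was compared with counting noise in 54 pairs, using genes with a summed count of at least 20. Chi-square over degrees of freedom ran from 1.86 to 17.7, so no pair lay within sampling noise. The main test was tested on simulated data in which 200 genes were changed. It recovered 17% to 57% of genes changed 2-fold and 73% to 91% of those changed 4-fold, with 0.73% to 9.62% false calls. Analyses used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures matplotlib 3.10.9.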

Results

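Transcripts were counted by bulk 3′ RNA sequencing (MARS-seq, which reads transcripts from their 3′ ends) in 50 mouse libraries that fell into 16 groups of sorted cells. The first set held 8 groups of 3 libraries from lymph nodes. These were ILC3 (group 3 innate lymphoid cells, lymphocytes without rearranged antigen receptors), MHC class II positive ILC3 (MHCII+ ILC3), ILC3 positive for a GFP reporter of the autoimmune regulator Aire (Aire-GFP+ ILC3) and dendritic cells (DC), each nonstimulated or after heat-killed Candida albicans. A separate set held Candida-stimulated Aire-GFP+ ILC3 labelled Aire WT or Aire KO, with 3 libraries each. The remaining set held OTII T cells (CD4 T cells with a transgenic receptor for an ovalbumin peptide) after Candida albicans, sorted as nonproliferating, proliferating or Rorc-GFP+ cells. Their genotype was given as Aire-flox without Rorc-cre (WT) or with Rorc-cre (KO), with 3 libraries per group except for 4 in each of the KO proliferating and KO Rorc-GFP+ groups.

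Total counts per library ran from 1134610 to 1499865 in nonstimulated ILC3, 1200202 to 1836138 in stimulated ILC3, 1266882 to 1749045 in nonstimulated MHCII+ ILC3 and 1304284 to 1912364 in stimulated MHCII+ ILC3. Nonstimulated Aire-GFP+ ILC3 had 534107 to 3204733 counts and stimulated ones 485052 to 1263001, while DC had 2065818 to 2320150 without and 3677124 to 3960539 with Candida. In the Aire WT and KO set the totals were 485105 to 1464133 and 910876 to 2024201. Among WT OTII cells the totals were 834159 to 1797801 (nonproliferating), 453421 to 1856823 (proliferating) and 918575 to 1359991 (Rorc-GFP+). The KO OTII groups had 1391212 to 1797147, 724583 to 2696376 and 131327 to 450606 counts in the same order, so that KO Rorc-GFP+ cells were the shallowest group. The labels call the libraries biological replicates without saying whether each came from its own animal, and p-values here measure the spread between these libraries. Adjusted p-values for genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes of a comparison, and those for gene lists from limma's camera test adjusted over the lists of a comparison. Where an estimated value follows, it is the adjusted p of that test with a correlation between genes estimated from the libraries. In nonstimulated Aire-GFP+ ILC3, nonstimulated DC and KO nonproliferating OTII cells the numbers of the count columns do not match the replicate numbers of the labels, so these libraries are called a, b and c in column order.

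The transcriptome of Aire-GFP+ ILC3 in homeostasis was set against that of ILC3. Aire, a regulator of tissue antigen expression in the thymus, averaged 444 ± 49 CPM (SD, n = 3) in nonstimulated Aire-GFP+ ILC3 and 1.11 ± 1.47 in ILC3, a log2 fold change of 8.58 (SE 0.39, adjusted p = 1.05e-19). Antigen-presentation transcripts were far higher in the same cells. H2-Aa, a chain of MHC class II, reached 12900 ± 1460 CPM against 211 ± 91.6 (log2 fold change 5.92), and the costimulatory receptor gene Cd40 reached 757 ± 76.3 against 7.20 ± 2.20 (6.68). In mm10, Aire lies on chromosome 10 from 78030022 to 78043610 and Icosl, which encodes the ligand of ICOS, on chromosome 10 from 78069302 to 78083913. Cd40 lies on chromosome 2 from 165055627 to 165072948 and H2-Aa on chromosome 17 from 34282744 to 34287823. In all, 5539 of 10568 tested genes differed, 2652 higher and 2887 lower in Aire-GFP+ ILC3.

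All 14 tested genes of MHC class II presentation were higher in Aire-GFP+ ILC3 than in ILC3 (median log2 fold change 4.85, adjusted p = 6.14e-23), among them the invariant chain Cd74 (5.88), the lysosomal reductase Ifi30 (5.12) and the peptide exchange factor H2-DMb1 (4.50). All 18 genes of DC maturation were higher as well (median 2.85, adjusted p = 1.18e-14), with the lymph node homing receptor Ccr7 at 3.55, Marcksl1 at 4.37 and the NF-kB subunit Relb at 2.93. Of 15 costimulatory and checkpoint ligands 12 were higher and 2 lower (adjusted p = 2.03e-08), including Icosl (5.79), Cd80 (5.39) and Cd86 (5.16). Genes of RANK, CD40 and NF-kB signalling were higher in 16 of 19 cases and lower in 1 (adjusted p = 5.75e-09). DC identity genes were higher in 11 of 15 cases and lower in 1 (adjusted p = 2.01e-05), with the transcription factor Batf3 at 5.21 and the integrin Itgax at 1.18. Itgax missed the threshold without ILC3 nonstimulated replicate 3 (log2 fold change 0.97, adjusted p = 0.0578). Il12b, the p40 chain of IL-12 and IL-23, was higher (6.89), as was the cytokine subunit Ebi3 (5.07), while Il6 was lower (−4.70).

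Of 23 genes of the ILC3 program, 18 were lower and 5 higher in Aire-GFP+ ILC3 (median −1.57, adjusted p = 0.000256). The lineage factor Rorc stood at 44.2 ± 17.1 CPM against 143 ± 5.48 (log2 fold change −1.57, adjusted p = 2.52e-07), the IL-7 receptor gene Il7r at −3.03, the chemokine receptor Cxcr6 at −6.01 and Thy1 at −3.07, whereas the stem cell factor receptor Kit was higher (2.95). Type I interferon response genes were lower in 21 of 24 cases and higher in 2 (median −2.72, adjusted p = 1.77e-06, estimated 0.0582). Ifit1 stood at −3.83 and Irf7 at −2.67, while Mx1 was higher at 2.9. Inflammatory chemokines were lower in 10 of 14 cases and higher in 4 (adjusted p = 0.0249, estimated 0.144), with Ccl2 at −8.40 and Ccl7 at −9.05. T cell markers summed to 1810 ± 165 CPM in ILC3 and 77.8 ± 27.3 in Aire-GFP+ ILC3, with 10 of 11 lower (Cd3e −5.10, Cd247 −4.54), and stromal markers to 5070 ± 247 against 23.7 ± 8.71, with all 12 lower (Bgn −7.83). NK and ILC1 markers were lower in 10 of 11 cases (Nkg7 −4.97, Eomes −4.55, adjusted p = 1.21e-06) and higher in 1, the abundant chemokine gene Ccl5 (1.26), named after its values were seen. They summed to 5430 ± 1730 CPM in Aire-GFP+ ILC3 and 3870 ± 358 in ILC3. Plasma cell markers were higher in 5 of 7 cases and lower in 1 (median 2.61, adjusted p = 0.0772) and summed to 2140 ± 922 against 539 ± 8.39 CPM, and macrophage markers went both ways, with 2 of 14 higher and 2 lower (247 ± 54.9 against 426 ± 63.8 CPM). Mgp had no count in Aire-GFP+ ILC3 and was at least 198-fold lower there, taking a floor of 3 counts over the group. Myl7 and Tmem45b had no count in ILC3 and were at least 79.9-fold and 39-fold higher in Aire-GFP+ ILC3.

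MHCII+ ILC3 and ILC3 differed in 4303 genes, 2136 higher and 2167 lower in MHCII+ ILC3. Antigen-presentation genes were higher, at lower levels than in Aire-GFP+ ILC3, as were cell cycle and plasma cell genes. Of 14 MHC class II presentation genes 13 were higher and none lower (median 3.17, adjusted p = 7.39e-20), including H2-Aa (4.23, 3990 ± 640 against 211 ± 91.6 CPM), Cd74 (4.37) and Ifi30 (3.72). DC maturation genes were higher in 15 of 18 cases (17 when adjusted over the list alone, adjusted p = 9.55e-11), such as Ccr7 (2.33) and the chemokine Ccl22 (6.48). Costimulatory and checkpoint ligands were higher in 9 of 15 cases and lower in 1 (adjusted p = 8.42e-07), with Cd40 at 4.84, Cd80 at 3.47 and Icosl at 2.86. DC identity genes were higher in 7 of 15 cases (adjusted p = 0.000253), including Batf3 (4.27) and the growth factor receptor Flt3 (5.25). Aire itself averaged 18.2 ± 5.20 CPM against 1.11 ± 1.47 (log2 fold change 3.97, SE 0.52, adjusted p = 1.28e-07).

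In MHCII+ ILC3, 25 of 28 cell cycle genes were higher than in ILC3 (median 2.26, adjusted p = 3.57e-20), among them Ube2c (2.5), Rrm1 (1.92) and Bub1b (2.83). Whether plasma cells in the sort carried these, before or after stimulation, was not tested. All 7 plasma cell markers were higher (median 4.51, adjusted p = 6.90e-11), with Mzb1 at 7, Jchain at 5.96, Derl3 at 5.80 and Xbp1 at 2.06. They summed to 11500 ± 1810 CPM in MHCII+ ILC3, 539 ± 8.39 in ILC3 and 2140 ± 922 in Aire-GFP+ ILC3. B cell markers were higher in 5 of 10 cases and lower in 1 (7 and 1 when adjusted over the list alone, adjusted p = 0.00123, estimated 0.144), with Cd79b at 2.37 and Cd19 at 2.32. T cell markers were lower in 9 of 11 cases and higher in 1 (Cd5 −3.69, Cd6 −3.57), and all 12 stromal markers were lower (Col1a2 −3.75, Col3a1 −4.26). Genes of the type I interferon response were lower in 17 of 24 cases and higher in 3 (Ifit1 −2.72, adjusted p = 7.96e-05, estimated 0.0565). ILC3 program genes were lower in 11 of 23 cases and higher in 4 (adjusted p = 0.0473, estimated 0.144), with Il7r at −1.70, the transcription factor Tcf7 at −1.33 and Id2, a repressor needed for innate lymphoid development, at 1.72. Rorc stood at −0.56 (adjusted p = 0.0334) and missed the threshold without ILC3 nonstimulated replicate 1 (−0.56, adjusted p = 0.0690), replicate 2 (−0.53, 0.0890) or replicate 3 (−0.58, 0.0596), and without MHCII+ nonstimulated replicate 2 (−0.47, 0.130) or replicate 3 (−0.57, 0.0636). Large differences with no overlap between libraries included Slpi, a secreted protease inhibitor (7.33, 9280 ± 992 against 58.2 ± 27.0 CPM), the calcium channel gene Cacna1s (7.34) and Eaf2 (7.46).

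Aire-GFP+ ILC3 and MHCII+ ILC3 differed in 4357 genes, 2037 higher and 2320 lower in Aire-GFP+ ILC3. Antigen-presentation, maturation and NF-kB genes were higher still in Aire-GFP+ ILC3, and every tested cell cycle gene was lower. Aire was 4.61 log2 units higher (SE 0.26, adjusted p = 1.41e-15). MHC class II presentation genes were higher in 13 of 14 cases (median 1.57, adjusted p = 8.63e-11), with H2-Aa at 1.69, H2-DMb1 at 2.25 and H2-DMb2 at 2.73. DC maturation genes were higher in 17 of 18 cases (adjusted p = 2.28e-07), including the signalling adaptor Traf1 (1.93), the tetraspanin Cd63 (1.67) and Relb (1.31). Genes of RANK, CD40 and NF-kB signalling were higher in 14 of 19 cases (17 when adjusted over the list alone, adjusted p = 1.25e-07), such as Bcl3 (1.37) and Nfkbie (1.13). Costimulatory and checkpoint ligands were higher in 10 of 15 cases and lower in 2 (adjusted p = 8.92e-05), with Icosl at 2.93, Cd86 at 2.80 and Cd40 at 1.84. All 28 cell cycle genes were lower (median −1.71, adjusted p = 2.43e-15), among them Rrm2 (−2.43), Tk1 (−2.53) and Mcm6 (−1.71), genes of DNA synthesis. In the ILC3 program 12 of 23 genes were lower and 2 higher (13 and 2 when adjusted over the list alone, adjusted p = 0.00148). Rorc stood at −1.01, Il7r at −1.33, Cxcr6 at −4.69 and the transcription factor Gata3 at −3.02, whereas Tcf7 was higher (1.79).

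Between the same groups, plasma cell markers were lower in 5 of 7 cases in Aire-GFP+ ILC3 (all 7 when adjusted over the list alone, adjusted p = 1.02e-05), with Derl3 at −3.19, Sdc1 at −2.74 and Xbp1 at −2.03. B cell markers were lower in 8 of 10 cases and higher in 1 (Cd79b −1.5, Fcer2a 2.61, adjusted p = 0.00918, estimated 0.258). T cell markers were lower in 6 of 11 cases and higher in 1 (Cd3e −3.96, Cd3g −4.09), NK and ILC1 markers in 8 of 11 (Nkg7 −3.92), and all 12 stromal markers were lower (Col1a2 −5.06, Bgn −5.07). Type I interferon response genes were lower in 11 of 24 cases and higher in 2 (Zbp1 −2.96, Irf7 −1.90, adjusted p = 0.00605, estimated 0.184). Large differences included Iglon5 (5.68) and Lingo1 (5.23), both neuronal surface proteins, the ileal bile acid binding protein Fabp6 (5, 101 ± 37.3 against 2.98 ± 0.742 CPM) and Dnmt3l, a cofactor of DNA methylation in germ cells (4.99). The annotated spans of Aire (minus strand) and Dnmt3l (plus strand, 78041947 to 78063622) overlap on chromosome 10 at the 5′ ends of both. Tags come from 3′ ends, and whether counting used the strand is not given in the sources used here. On the lower side the muscle actinin Actn2 stood at −6.30. The related list of tissue-restricted antigens had 4 of its 40 genes tested in these cells, with 1 higher and 2 lower in Aire-GFP+ than in MHCII+ ILC3 (median −1.49, adjusted p = 0.372, summed 25.5 ± 9.55 against 58.1 ± 14.5 CPM), and 2 higher in MHCII+ ILC3 than in ILC3 (adjusted p = 0.0490, estimated 0.0981).

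Aire-GFP+ ILC3 were set against DC as well, and the comparison of both groups in homeostasis called 5607 genes, 2912 higher and 2695 lower in Aire-GFP+ ILC3. DC identity genes were lower in 11 of 15 cases and higher in 3 (12 and 3 when adjusted over the list alone, median −3.32, adjusted p = 3.49e-12), with Itgax at 13.9 ± 5.39 against 619 ± 74.9 CPM (log2 fold change −5.30, SE 0.29, adjusted p = 3.29e-16), Cst3 at −3.33 and the lectin Cd209a at −5.97. In the ILC3 program 16 of 23 genes were higher and 1 lower (17 and 1 when adjusted over the list alone, adjusted p = 5.74e-05). Rorc stood at 3.56, Tcf7 at 4.61, Ccr6 at 2.58, Il1r1 at 2.92 and Il7r at 1.02. DC maturation genes were higher in 15 of 18 cases and lower in 1 (median 1.99, adjusted p = 2.10e-09), for example Tmem123 (3.69), Il15ra (3.64) and the apoptosis inhibitor Birc2 (2.95). Of 14 MHC class II presentation genes 12 were lower and none higher (median −1.22, adjusted p = 0.000280, estimated 0.252), with H2-Aa at −1.86, Cd74 at −1.46, H2-DMb1 at −2.24 and H2-DMa at −1.95. Costimulatory and checkpoint ligands went both ways, with 7 of 15 higher and 6 lower (adjusted p = 0.213), such as Cd200 (4.98) and the OX40 ligand Tnfsf4 (4.86) on the higher side and Lgals9 (−3.15) on the lower.

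Fungal sensing genes were lower in Aire-GFP+ ILC3 than in DC in 11 of 16 cases and higher in none (median −2.22, adjusted p = 5.72e-05, estimated 0.132). Examples were the inflammasome sensor Nlrp3 (−4.27), the receptor Tlr2 (−2.95) and the adaptor Myd88 (−2.27). Genes of the type I interferon response were lower in 18 of 24 cases and higher in 2 (median −2.5, adjusted p = 5.61e-08), with Irf7 at −3.99 and Oasl1 at −4.31. Inflammatory chemokines were lower in 9 of 14 cases and higher in 3 (adjusted p = 0.000280), including Ccl4 (−7.81), Ccl3 (−6.08) and Cxcl9 (−4.86). All 14 monocyte and macrophage markers were lower (median −4.41, adjusted p = 5.86e-06, estimated 0.249), with Csf1r at −6.30 and Cd14 at −5.44. They summed to 4480 ± 1520 CPM in nonstimulated DC and 247 ± 54.9 in Aire-GFP+ ILC3. Lingo1 and Cacng4 had no count in DC and were at least 101-fold and 80.2-fold higher in Aire-GFP+ ILC3, and Ear2 and Plet1 had no count in Aire-GFP+ ILC3 and were at least 76.1-fold and 116-fold lower there.

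**Figure D1:**
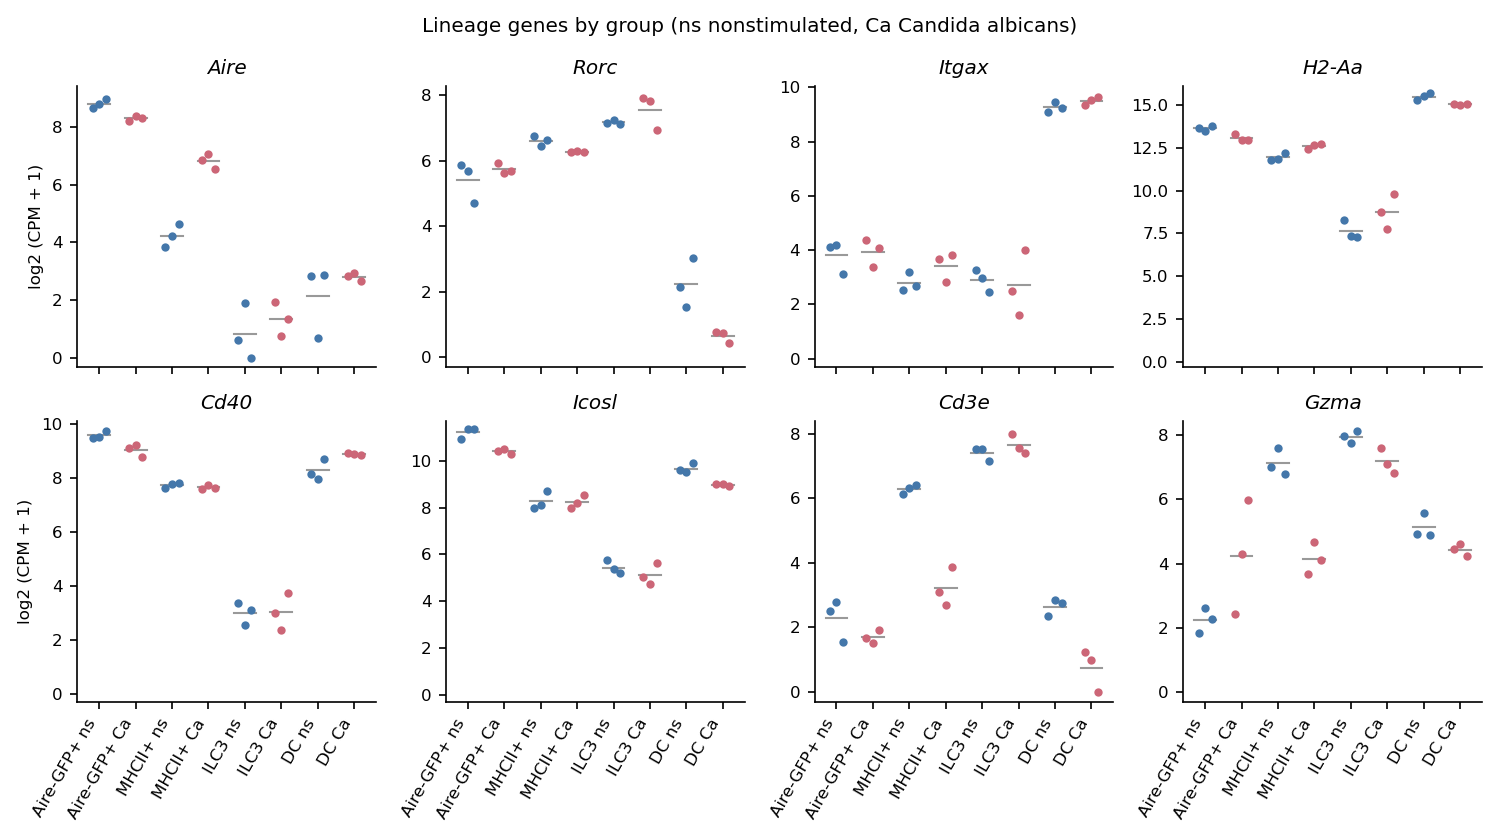
Log2(CPM + 1) of Aire, Rorc, Itgax, H2-Aa, Cd40, Icosl, Cd3e and Gzma in the 8 groups of ILC3 and DC; points are libraries (blue nonstimulated, red after Candida albicans, n = 3 per group) and grey lines the mean of the log2 values. Aire averaged 444 CPM in nonstimulated Aire-GFP+ ILC3 and 1.11 in ILC3, and Itgax 619 CPM in nonstimulated DC and 13.9 in Aire-GFP+ ILC3.

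The response of Aire-GFP+ ILC3 to Candida albicans comprised 696 genes, 423 higher and 273 lower after stimulation. Ccl2 rose from 6.29 ± 1.30 to 47.5 ± 30.8 CPM (log2 fold change 2.92, SE 0.49, adjusted p = 0.00132), and Cxcr6 from 4.97 ± 0.847 to 27.1 ± 18.8 CPM (2.55, SE 0.43, adjusted p = 0.000651). The liver-type phosphofructokinase Pfkl fell from 1110 ± 231 to 407 ± 9.46 CPM (−1.45, SE 0.18, adjusted p = 9.75e-06) and Slpi from 1120 ± 198 to 178 ± 69.3 CPM (−2.62, SE 0.47, adjusted p = 0.00333). Aire itself was at 312 ± 18.4 CPM against 444 ± 49 (log2 fold change −0.50, adjusted p = 0.143), Rorc at 0.16 (adjusted p = 0.743) and H2-Aa at −0.56 (adjusted p = 0.315). Ccl2 lies on chromosome 11 from 82035571 to 82037453 and Pfkl on chromosome 10 from 77986947 to 78010083.

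Among inflammatory chemokines 3 of 14 rose in stimulated Aire-GFP+ ILC3 and none fell (adjusted p = 0.0380, estimated 0.388), Ccl4 among them (1.48), which missed the threshold without Candida replicate 1 (0.91, adjusted p = 0.194). Type I interferon response genes rose in 7 of 24 cases (9 when adjusted over the list alone, adjusted p = 0.00180, estimated 0.388), including the antiviral genes Ifit1 (2.09) and Oasl1 (1.81). In the ILC3 program 3 of 23 genes rose (5 when adjusted over the list alone, adjusted p = 0.0202, estimated 0.388), among them Il7r (1.22, SE 0.26, adjusted p = 0.00317). Without nonstimulated library b Il7r was at 0.92 (adjusted p = 0.0696). MHC class II presentation genes fell in 3 of 14 cases and rose in none (median −0.48, adjusted p = 0.00180, estimated 0.388). H2-DMa stood at −0.64 and H2-DMb1 at −0.65. H2-DMa missed the threshold without nonstimulated library b (adjusted p = 0.123), Candida replicate 1 (0.0748) or Candida replicate 2 (0.133), and H2-DMb1 without the same libraries (0.138, 0.114 and 0.0902). Icosl fell by 0.83 on the log2 scale (adjusted p = 0.00682), with −0.76 (adjusted p = 0.0591) without library b. Tnfrsf11a, which encodes RANK, rose (1.16, adjusted p = 0.00821), with 0.92 (adjusted p = 0.113) without library b. The NF-kB cofactor Bcl3 stood at −0.76, the cytokine signalling inhibitor Socs1 at −0.98 and the maturation gene Marcksl1 at −1.11. Il6 rose (1.80, adjusted p = 0.00783), with 1.39 (adjusted p = 0.0840) without library b and 1.49 (adjusted p = 0.0537) without Candida replicate 3. Clec7a, which encodes the β-glucan receptor Dectin-1, rose by 1.21 (adjusted p = 0.0481) and missed the threshold without any 1 of the 6 libraries, with adjusted p between 0.0582 and 0.186.

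Early-response and dissociation genes fell in 4 of 19 cases and rose in 1 (adjusted p = 0.0138, estimated 0.424), with Jund at −1.54 and the chaperone Hsp90aa1 at 2.16. Stromal markers were higher in 2 of 12 cases (adjusted p = 0.00180, estimated 0.388), Dcn among them at 2.67, and summed to 86.7 ± 44.5 CPM after and 23.7 ± 8.71 before stimulation. T cell markers summed to 87.4 ± 33.4 and 77.8 ± 27.3 CPM. Monocyte and macrophage markers were higher in 2 of 14 cases (median 1.59) and summed to 494 ± 543 CPM after and 247 ± 54.9 before stimulation, with neutrophil markers at 136 ± 160 and 37.7 ± 58.3 CPM. Mast cell and basophil markers had none called over all genes (4 of 4 higher when adjusted over the list alone, median 4.32 with 1 gene at the bound of 3 counts) and summed to 43.7 ± 73 and 3.88 ± 2.09 CPM. In the last 3 lists 1 stimulated library held most of the rise (1120, 320 and 128 CPM, lowest 163, 26.1 and 0). Atg9b (−2.04) and Hdac3 (−1.97) fell too. Across 4434 genes, which are not independent replicates, log2 fold changes after stimulation correlated with transcript GC content at r = −0.43. The count of 696 genes was 1216 and 190 without nonstimulated libraries a and b, and 381 without Candida replicate 2. It was 228 in a fit of these libraries alone, 336 with the GC offset and 333 without both shallow libraries. With the GC offset Il7r was at 0.69 (adjusted p = 0.0627), Il6 at 1.22 (0.0898) and Bcl3 at −0.36 (0.217). Without the shallow libraries Bcl3 was at −0.63 (0.0876) and Dcn at 2.30 (0.0568).

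In MHCII+ ILC3, 1442 genes were called after Candida albicans, 619 higher and 823 lower. Aire rose from 18.2 ± 5.20 to 113 ± 21.2 CPM (log2 fold change 2.64, SE 0.26, adjusted p = 1.31e-08). Fabp6 rose from 2.98 ± 0.742 to 109 ± 11 CPM (5.19, SE 0.56, adjusted p = 2.61e-06) and Tnfrsf11b, the decoy receptor of RANK ligand, from 6.61 ± 0.593 to 48.2 ± 2.63 CPM (2.85, SE 0.32, adjusted p = 1.18e-07). The signalling chain Cd3e of the T cell receptor complex fell from 77 ± 8.22 to 8.90 ± 4.13 CPM (−3.10, SE 0.27, adjusted p = 1.84e-09), and the scavenger receptor gene Cd163l1 from 414 ± 29.4 to 35.6 ± 8.51 CPM (−3.53, SE 0.33, adjusted p = 1.18e-07). Fabp6 lies on chromosome 11 from 43596049 to 43601540 and Cd3e on chromosome 9 from 44998740 to 45009627. Rorc (−0.34, adjusted p = 0.309), H2-Aa (0.65, adjusted p = 0.184), Itgax (0.70, adjusted p = 0.278) and Il7r (−0.03, adjusted p = 0.952) missed the threshold, and H2-Aa passed in a fit of these libraries alone (0.69, adjusted p = 0.00851).

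In stimulated MHCII+ ILC3, 6 of 14 MHC class II presentation genes rose and none fell (7 when adjusted over the list alone, median 0.57, adjusted p = 7.85e-05, estimated 0.199), including H2-DMb1 (0.83) and H2-DMb2 (1.45). Costimulatory and checkpoint ligands rose in 3 of 15 cases and fell in 1, with Cd86 at 1.62 and Cd274, which encodes PD-L1, at −1.27. ILC3 program genes went both ways, with 5 of 23 higher and 5 lower (adjusted p = 0.523), such as Cxcr5 (1.55), Kit (1.21) and the RANK ligand Tnfsf11 (1.76) against Id2 (−1.12). Cell cycle genes fell in 19 of 28 cases and rose in none (20 when adjusted over the list alone, median −0.80, adjusted p = 3.33e-13, estimated 0.102), among them Ube2c (−1.27), Bub1b (−1.37) and Plk1 (−1.49). Inflammatory chemokines fell in 6 of 14 cases (7 when adjusted over the list alone, adjusted p = 0.00613, estimated 0.102), with Ccl2 at −1.42. Genes of the type I interferon response rose in 6 of 24 cases and fell in 2 (7 and 3 when adjusted over the list alone, adjusted p = 0.00190, estimated 0.181), with Oasl1 at 1.57. In the interferon-gamma response Irgm1 rose (1.13) and Irf1 fell by 0.65 on the log2 scale, and Il12b stood at −1.5.

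In the same MHCII+ ILC3 libraries T cell markers fell in 4 of 11 cases and rose in none (median −0.66, adjusted p = 5.39e-10, estimated 0.0787), these being Cd3e, Cd3g (−2.99), Cd3d (−2.58) and Cd247 (−2.5), and summed to 512 ± 30.3 CPM before and 157 ± 10.5 after stimulation. Sox13, a transcription factor of gamma-delta T cells, stood at −3.27 and the actin regulator Avil at −4.64. NK and ILC1 markers fell in 6 of 11 cases (1 higher and 6 lower when adjusted over the list alone, adjusted p = 0.00190, estimated 0.102), such as Gzma (−3), Nkg7 (−1.79) and Tbx21 (−1.34), and stromal markers in 7 of 12 (Col3a1 −2.49, adjusted p = 3.56e-06, estimated 0.102). B cell markers rose in 5 of 10 cases (6 up and 1 down when adjusted over the list alone, adjusted p = 8.52e-06, estimated 0.102), with Ms4a1 at 2.53, Cd19 at 1.47 and Fcer2a at 1.57, and summed to 554 ± 11.7 before and 944 ± 178 CPM after. Mast cell and basophil markers had none of 4 called and summed to 69.4 ± 23.4 CPM before and 166 ± 29.9 after stimulation. Plasmacytoid DC markers rose in 1 of 9 cases (adjusted p = 0.0348, estimated 0.341) and summed to 323 ± 49.4 and 604 ± 58 CPM, and the 1 tested erythroid marker rose (0.87), with sums of 49 ± 9.75 and 95.9 ± 9.68 CPM. Plasma cell markers fell in 3 of 7 cases (Derl3 −1.27, adjusted p = 0.0133, estimated 0.377). The count of 1442 genes in MHCII+ ILC3 was 862 without nonstimulated replicate 2, 642 without nonstimulated replicate 3, and 884, 857 and 714 without Candida replicates 1, 2 and 3.

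ILC3 showed 16 called genes after Candida albicans, 5 higher and 11 lower. The invariant chain Cd74 rose from 279 ± 70.8 to 779 ± 408 CPM (log2 fold change 1.48, SE 0.24, adjusted p = 0.00111) and the lectin Lgals3 from 160 ± 10.9 to 342 ± 44.7 CPM (1.09, SE 0.18, adjusted p = 0.00111). The collagen gene Col3a1 fell from 395 ± 84.1 to 117 ± 37.3 CPM (−1.77, SE 0.26, adjusted p = 0.00111) and the carbonic anhydrase Car2 from 100 ± 9.31 to 39.9 ± 12 CPM (−1.31, SE 0.21, adjusted p = 0.00111). Of 14 MHC class II presentation genes 1 rose (6 when adjusted over the list alone, median 0.56, adjusted p = 9.31e-10), and H2-Aa was at 1.27 (adjusted p = 0.164). Summed MHC class II presentation genes were at 1500 ± 455 CPM before and 3060 ± 1680 after stimulation. Glycolysis had no gene called over all genes (8 of 14 when adjusted over the list alone, median 0.54, adjusted p = 3.82e-08), with Ldha at 0.56 (adjusted p = 0.171) and the glucose transporter Slc2a1 at 0.98 (adjusted p = 0.131). NK and ILC1 markers had none called over all genes (6 of 11 lower when adjusted over the list alone, median −0.75, adjusted p = 7.52e-09), with Klrd1 at −1.26 (adjusted p = 0.107) and Eomes at −1.03 (adjusted p = 0.136). Stromal markers fell in 3 of 12 cases (5 lower and 1 higher when adjusted over the list alone, adjusted p = 6.26e-09), and summed to 5070 ± 247 CPM before and 3450 ± 512 after stimulation. Endothelial markers summed to 1200 ± 366 and 355 ± 177 CPM, and erythroid markers to 121 ± 13.5 and 44.9 ± 14.9 CPM. No marker of B cells, plasma cells or macrophages was called over all genes, with medians of 0.8 (adjusted p = 3.00e-04, estimated 0.160), 0.85 (0.00633 and 0.323) and 0.63 (0.0183 and 0.522). Type I interferon response genes had none of 24 called over all genes (2 higher when adjusted over the list alone, adjusted p = 3.74e-05, estimated 0.0625). Aire (0.71, adjusted p = 0.865), Rorc (0.46, adjusted p = 0.542), Itgax (−0.01, adjusted p = 1) and Il7r (−0.57, adjusted p = 0.421) missed the threshold.

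The count of 16 genes in ILC3 was 5 (3 higher), 10 and 8 without nonstimulated replicates 1, 2 and 3, and 6, 14 (8 higher) and 108 (65 higher and 43 lower) without Candida replicates 1, 2 and 3. DESeq2 called 34 genes, 26 higher and 8 lower, and a fit of these libraries alone 10, in which Cd74 was at 1.5 (adjusted p = 0.322). With DESeq2 Ldha (adjusted p = 0.00992), Slc2a1 (0.0411) and H2-Aa (0.0418) passed. Without Candida replicate 3 Il7r passed at −0.88 (adjusted p = 0.0357), Slc2a1 at 1.34 (adjusted p = 6.81e-05), Klrd1 at −2.07 (adjusted p = 1.03e-05) and Eomes at −1.32 (adjusted p = 0.0138). Without Candida replicate 2 H2-Aa passed at 1.64 (adjusted p = 0.000908).

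In DC, whose libraries were the deepest of this set after stimulation, Candida albicans changed 3710 genes, 1879 higher and 1831 lower. Clec7a rose from 293 ± 70.9 to 1360 ± 63.1 CPM (log2 fold change 2.21, SE 0.32, adjusted p = 1.86e-05) and the maturation gene Tmem123 from 111 ± 13.1 to 656 ± 88.8 CPM (2.56, SE 0.21, adjusted p = 2.71e-10). DC maturation genes rose in 11 of 18 cases and fell in none (12 when adjusted over the list alone, median 1.15, adjusted p = 2.84e-08, estimated 0.0715), including Il15ra (2.30), Samsn1 (1.79) and Cd63 (1.44). Costimulatory and checkpoint ligands rose in 8 of 15 cases and fell in 3 (adjusted p = 0.137), with Cd24a at 2.11, Cd200 at 2.14 and the maturation marker Cd83 at 1.19. Fungal sensing genes rose in 6 of 16 cases and fell in 3 (median −0.24, mean 0.30, list test not passing), with the mannose receptor Mrc1 at 2.54 and the signalling protease Malt1 at 1.35 against Nlrp3 at −1.32. Type I interferon response genes rose in 9 of 24 cases and fell in 2 (adjusted p = 0.0159, estimated 0.510), with Oasl2 at 2.31 and Mx1 at 1.60. Interferon-gamma response genes rose in 10 of 23 cases and fell in 2 (11 and 2 when adjusted over the list alone, adjusted p = 0.0151, estimated 0.257), with Irgm1 at 2.37, Gbp3 at 2.25 and Ifi47 at 1.96. In RANK, CD40 and NF-kB signalling 6 of 19 genes rose and 2 fell (7 and 3 when adjusted over the list alone), such as Tnfrsf11a (2.96) and Nfkb1 (1.13).

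Inflammatory chemokines in stimulated DC rose in 4 of 14 cases and fell in 7, with Ccl4 at −1.19, Ccl7 at −2.42 and Xcl1 at −2.13. Cell cycle genes fell in 10 of 28 cases and rose in 3 (13 and 3 when adjusted over the list alone, adjusted p = 0.0639). Il7r rose from 22.5 ± 4.64 to 107 ± 9.16 CPM (2.25, SE 0.26, adjusted p = 6.36e-08), Ifi203 (3.64) and Vsig10 (3.60) rose steeply, and the clock gene Per1 stood at −2.13. Aire (0.50, adjusted p = 0.396), H2-Aa (−0.46, adjusted p = 0.276) and Itgax (0.24, adjusted p = 0.404) missed the threshold, while H2-Aa (−0.40, adjusted p = 0.00190) and Itgax (0.31, adjusted p = 0.0340) passed in a fit of these libraries alone. Rorc fell from 4.13 ± 2.71 to 0.566 ± 0.182 CPM (−2.68, adjusted p = 0.00169). In the same DC libraries T cell markers were lower in 6 of 11 cases (Cd3g −3.63, Cd5 −1.56, adjusted p = 0.0129, estimated 0.510) and stromal markers in 7 of 12 (10 when adjusted over the list alone, Dcn −3.07, Sparc −3.33, adjusted p = 0.00152, estimated 0.487). They summed to 219 ± 23 and 49.7 ± 11.6 CPM before and 131 ± 6.51 and 11.8 ± 1.63 CPM after stimulation, and macrophage markers to 4480 ± 1520 and 2460 ± 90.2 CPM. Across 4434 genes log2 fold changes of DC correlated with transcript GC content at r = −0.40.

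**Figure D2:**
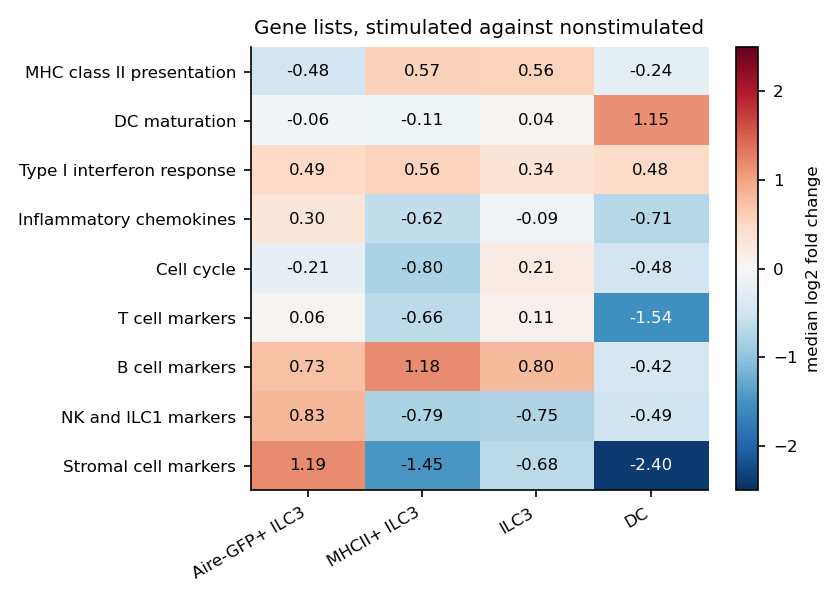
Median log2 fold change after Candida albicans (colour and printed value) of 9 gene lists in each of the 4 sorted populations, n = 3 libraries per group, with genes that had no count in a group set at the bound of 3 counts. MHC class II presentation was at −0.48 in Aire-GFP+ ILC3, 0.57 in MHCII+ ILC3, 0.56 in ILC3 and −0.24 in DC.

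Whether the populations responded differently was tested as a difference of differences. Against MHCII+ ILC3, 285 genes responded differently in Aire-GFP+ ILC3, 123 with the higher and 162 with the lower log2 fold change. The response of Aire was far below that in MHCII+ ILC3 (difference −3.14, SE 0.34, adjusted p = 1.20e-07). MHC class II presentation genes had the lower response in 6 of 14 cases (11 when adjusted over the list alone, median −1.17, adjusted p = 4.64e-12), with H2-DMb1 at −1.48 and H2-DMb2 at −1.87. Inflammatory chemokines had the higher response in 2 of 14 cases (5 when adjusted over the list alone, adjusted p = 5.55e-07), these being Ccl2 (4.34) and Ccl7 (4.53). NK and ILC1 markers were higher in 3 of 11 cases (Gzma 5.93, Nkg7 2.47, adjusted p = 5.55e-07), stromal markers in 4 of 12 (Col1a2 4.67, Dcn 3.20, adjusted p = 2.45e-10), and T cell markers in 3 of 11 (Cd3d 2.95, Cd3g 2.80, adjusted p = 0.000151, estimated 0.223). Iglon5 (−4.53), Fabp6 (−4.23) and Lingo1 (−3.51) had a far lower response in Aire-GFP+ ILC3. Nkg7 missed the threshold without Aire-GFP+ Candida replicate 3 (1.57, adjusted p = 0.162), Cd3g without that library (1.98, adjusted p = 0.355) or Candida replicate 2 (2.60, adjusted p = 0.0653), and Dcn without nonstimulated library a (3.06, adjusted p = 0.0538). The count of 285 was 178 without Aire-GFP+ Candida replicate 3, 183 and 178 without MHCII+ Candida replicates 2 and 3, and 189 in a fit of these 4 groups alone.

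Against ILC3, 336 genes responded differently in Aire-GFP+ ILC3, 233 higher and 103 lower. Il7r (1.80), Cxcr6 (2.80) and Ccl2 (3.30) had the higher response, and Cd74 (−1.93), Pfkl (−1.73), Jund (−1.83) and Slpi (−3.94) the lower. MHC class II presentation genes had the lower response in 5 of 14 cases (9 when adjusted over the list alone, adjusted p = 1.02e-08, estimated 0.0958), glycolysis genes in 2 of 14 (5 when adjusted over the list alone, adjusted p = 0.000208, estimated 0.0958). Stromal markers had the higher response in 3 of 12 cases (Col1a2 4.33, adjusted p = 2.28e-05, estimated 0.133). H2-Aa was at −1.83 (adjusted p = 0.0312) and missed the threshold without any of 7 of the 12 libraries, with adjusted p from 0.0543 to 0.0917. Those were Aire-GFP+ nonstimulated libraries b and c, Aire-GFP+ Candida replicates 2 and 3, ILC3 nonstimulated replicates 2 and 3 and ILC3 Candida replicate 1. Ccl4 was at 1.83 and at 1.26 (adjusted p = 0.136) without Aire-GFP+ Candida replicate 1. Ccl7 was at 3.58 (adjusted p = 0.0156), with adjusted p of 0.0674, 0.0504 and 0.0870 without Aire-GFP+ nonstimulated library a, Candida replicate 2 and Candida replicate 3. The count of 336 was 680 without Aire-GFP+ nonstimulated library a, 106 without library b and 169 without Aire-GFP+ Candida replicate 2. It was 216, 205 and 205 without ILC3 nonstimulated replicates 1, 2 and 3, 147, 161 and 690 without ILC3 Candida replicates 1, 2 and 3, 142 in a fit of these 4 groups alone, 149 with the GC offset and 209 without both shallow libraries.

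Against DC, 1135 genes responded differently in Aire-GFP+ ILC3, 379 higher and 756 lower. DC maturation genes had the lower response in 11 of 18 cases (13 when adjusted over the list alone, median −1.33, adjusted p = 7.14e-12), with Marcksl1 at −2.40, Il15ra at −2.02, Tmem123 at −1.77 and Cd63 at −1.75. Cd40 (−1.10), Nfkb1 (−1.28) and the lipid-presenting Cd1d1 (−3.76) were lower too. Inflammatory chemokines had the higher response in 5 of 14 cases and the lower in 2 (7 and 3 when adjusted over the list alone, adjusted p = 0.00293, estimated 0.0847), including Ccl2 (4.14), Ccl4 (2.67) and Ccl7 (5.72). Cxcr6 was at 4.76, and stromal markers had the higher response in 7 of 12 cases (9 when adjusted over the list alone, Dcn 5.74, adjusted p = 9.87e-10). Rorc was at 2.84 (adjusted p = 0.00628) and at 2.17 (adjusted p = 0.0868) without nonstimulated DC library c. Il7r was at −1.03 (adjusted p = 0.0663), and passed at −1.33 (adjusted p = 0.0138) without Aire-GFP+ nonstimulated library b and at −1.26 (adjusted p = 0.0441) without nonstimulated DC library c. The count of 1135 was 727 without Aire-GFP+ nonstimulated library a.

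Calls in different populations were also set side by side, with no library shared between them. Aire-GFP+ and MHCII+ ILC3 shared 123 genes that rose and 73 that fell, against 24.8 and 21.3 for independent lists among 10568 genes. Of genes that rose in Aire-GFP+ ILC3 15 fell in MHCII+ ILC3, and of those that fell 21 rose there (32.9 and 16 for independent lists), and the log2 fold changes of all genes correlated at 0.21. Aire-GFP+ ILC3 and ILC3 shared 0 genes in either direction (0.2 and 0.284 for independent lists). The overlaps of Aire-GFP+ ILC3 with DC were 201 and 125 genes (75.2 and 47.3 for independent lists), and those of MHCII+ ILC3 with DC 267 and 363 (110 and 143). Fold changes fell with transcript GC content in Aire-GFP+ ILC3, MHCII+ ILC3 and DC alike (r = −0.43, −0.22 and −0.40), so the overlaps do not separate a shared response from a shared GC trend.

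The Aire KO libraries addressed which transcripts of stimulated Aire-GFP+ ILC3 depend on Aire. Aire itself was counted at 288, 370 and 342 CPM in Aire KO replicates 1, 2 and 3 and at 886, 790 and 993 CPM in Aire WT replicates, a log2 fold change of −1.42 (SE 0.22, adjusted p = 0.178). A 3′ tag outside the deleted part does not check the genotype, and the deletion's position is not given in the sources. No gene passed with edgeR (0 of 8540, with 17% of simulated 2-fold changes recovered), while 579 had an unadjusted p under 0.05, DESeq2 called 16 and the authors' deposited table lists 14. With DESeq2 Aire was at −1.43 (adjusted p = 1.71e-05), the B cell genes Cd22 at 2.67 and Cd19 at 2.53 (both adjusted p = 2.59e-05) and Blk at 2.60 (adjusted p = 0.000514), and the T cell gene Cd247 at 2.92 (adjusted p = 0.0137).

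All 9 B cell markers were higher when adjusted over the list alone and none over all genes (median 2.55, adjusted p = 1.29e-21, estimated 0.442), and they summed to 1430 ± 805 CPM in Aire KO and 461 ± 102 in Aire WT. T cell markers were higher in 8 of 9 cases when adjusted over the list alone (median 2.36, adjusted p = 1.81e-08, estimated 0.442), and summed to 484 ± 551 and 85.8 ± 15.8 CPM. Endothelial markers summed to 469 ± 746 CPM in Aire KO, with 1330 in replicate 1, and to 29 ± 18.7 in Aire WT. Without Aire KO replicate 1 the medians were 1.58 for B cell markers and 0.88 for T cell markers. Cell cycle genes had a median of 0.47 (adjusted p = 0.00188, estimated 0.617). DC maturation genes had a median of −0.35 (adjusted p = 0.000408, estimated 0.442), with Ccl22 at −0.75 (adjusted p = 0.729) and Marcks at −1.07 (adjusted p = 0.718), and NF-kB signalling genes one of −0.21 (adjusted p = 0.000533, estimated 0.442). Without Aire KO replicate 1 these were −0.11 (adjusted p = 0.236) and −0.08 (adjusted p = 0.116). Among costimulatory genes Cd80 was at −0.66 and Cd86 at −0.84 (both adjusted p = 0.718). Of 40 tissue-restricted antigens 2 had enough counts to be tested, Fabp1 at −1.86 (adjusted p = 0.655) and Tg at 1.46 (adjusted p = 0.729). The count of 0 became 8 without Aire KO replicate 2 and 1 without Aire WT replicate 3. Without Aire KO replicate 2 Cd22 passed at 3.08 (adjusted p = 0.0211), Cd19 at 2.88 (adjusted p = 0.0265) and Blk at 2.93 (adjusted p = 0.0265).

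**Figure D3:**
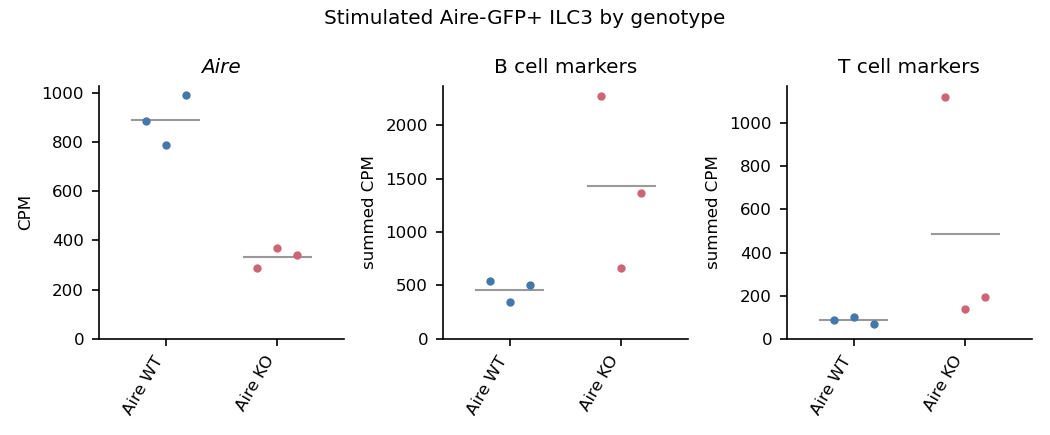
CPM of Aire (left) and the summed CPM of B cell (middle) and T cell markers (right) in stimulated Aire-GFP+ ILC3 labelled Aire WT or Aire KO; points are libraries (n = 3 each) and grey lines group means. Aire lay between 288 and 370 CPM in Aire KO and between 790 and 993 CPM in Aire WT libraries, and summed B cell markers between 665 and 2270 against 345 and 538 CPM.

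The OTII libraries addressed whether T cells primed with Candida albicans differ where RORγt-lineage cells carry floxed Aire with the Rorc-cre deleter. Aire, the targeted gene, has no line in the T cell counts, so the genotype was not checked in these libraries. In nonproliferating cells edgeR called 0 of 8739 genes between KO and WT (139 with an unadjusted p under 0.05, and 0 with DESeq2 and in the authors' deposited table). Treg program genes had a median of −0.55 (none of 11 called when adjusted over the list alone, adjusted p = 1.92e-05), with the folate receptor family member Izumo1r at 676 ± 279 CPM in KO and 1040 ± 138 in WT cells (log2 fold change −0.63, adjusted p = 1) and Gpr83 at −0.72 (adjusted p = 1). Cell cycle genes had a median of −0.46 (adjusted p = 6.22e-09, estimated 0.216) and T cell activation genes one of −0.37 (adjusted p = 5.37e-05, estimated 0.0607), including Irf4 at −0.87. B cell markers had a median of 0.73 (adjusted p = 1.92e-05, estimated 0.118). Rorc was at 14.3 ± 2.39 in KO and 15.4 ± 7.19 CPM in WT (−0.18, adjusted p = 1) and Tbx21, the Th1 lineage factor, at −1.01 (adjusted p = 1). Ifng had no count in either group.

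In proliferating OTII cells edgeR again called 0 of 8739 genes between KO and WT (235 with an unadjusted p under 0.05, 2 with DESeq2 and 2 in the authors' deposited table). Treg program genes had a median of −0.66 (4 of 11 lower and 1 higher when adjusted over the list alone, adjusted p = 8.74e-06), such as Izumo1r at 1050 ± 255 against 1620 ± 68.7 CPM (−0.62, adjusted p = 1), Gpr83 at −1.07 and Ebi3 at 1.06. Cell cycle genes had a median of −0.50 (adjusted p = 8.60e-06, estimated 0.370), with Mcm5 at −0.55, and T cell activation genes one of −0.46 (2 lower and 1 higher of 18 when adjusted over the list alone, adjusted p = 0.000297, estimated 0.0704), with Lag3 at −1.13 and Egr2 at −1.05. Il7r was at 67.3 ± 48.0 against 19.6 ± 2.61 CPM (1.64, adjusted p = 1) and the naive cell adhesion gene Sell at 0.52. Rorc was at 4.84 ± 3.17 CPM in KO and 5.36 ± 5.25 in WT (−0.27, adjusted p = 1), Tbx21 at −0.02 and Ifng at 0.33 (both adjusted p = 1).

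Rorc-GFP+ OTII cells, reporter-positive for the Th17 lineage factor, differed between genotypes in 33 genes, 10 higher and 23 lower in KO cells. Gins2, part of the replicative helicase, was at 6.44 ± 4.71 CPM in KO and 51.8 ± 32.4 in WT (log2 fold change −2.9, SE 0.62, adjusted p = 0.0327), the spindle protein Tacc3 at −1.97 and the replication licensing inhibitor Gmnn at −1.83. Cell cycle genes were lower in 1 of 27 cases (14 when adjusted over the list alone, median −1.19, adjusted p = 1.39e-13, estimated 0.175), with Mcm2 at −1.30 (adjusted p = 0.0580), Mcm7 at −1.19 (adjusted p = 0.0580) and Pcna at −1 (adjusted p = 0.0674). They summed to 990 ± 264 CPM in KO (n = 4) and 2040 ± 465 in WT (n = 3), with p = 0.0286 in a two-sided exact permutation test over 35 splits. Il2rb, a chain of the IL-2 receptor, was at −1.85 (adjusted p = 0.0246), Izumo1r at −1.08, Nfatc1 at −0.92, Isg15 at −1.08 and Jund at −1.52 (adjusted p = 0.0214). Monocyte and macrophage markers were higher in 1 of 16 cases (4 when adjusted over the list alone, median 0.48, adjusted p = 0.000204, estimated 0.175), with Ms4a7 at 1.13 (adjusted p = 0.0275) and C1qb at 0.90 (adjusted p = 0.0956). They summed to 15900 ± 2040 CPM in KO (n = 4) and 10400 ± 1100 in WT (n = 3), with p = 0.0571 in the same two-sided exact permutation test. Mt1 (1.5), Cyp27a1 (2.08), the complement gene C3 (1.23) and Pld3 (1.05) were higher. Of 7 tested Th17 program genes none passed over all genes (1 higher and 1 lower when adjusted over the list alone, median 0.19, adjusted p = 0.736), and Il17a and Il17f had no line in the T cell counts. Rorc was at 47.7 ± 37.3 CPM in KO and 29.9 ± 9.75 in WT (0.49, adjusted p = 0.700), Tbx21 at −1.10 (adjusted p = 0.510) and Ifng at 2.33 (adjusted p = 0.745). Gins2 lies on chromosome 8 from 120578633 to 120589304 and Ms4a7 on chromosome 19 from 11321039 to 11336146.

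The 33 genes of Rorc-GFP+ cells rested on single libraries. The count was 7, 0 and 102 without WT replicates 1, 2 and 3, and 16, 8, 0 and 165 without KO replicates 1, 2, 3 and 4. Each of Gins2, Tacc3, Gmnn, Il2rb, Izumo1r, Nfatc1, Isg15, Jund, Cyp27a1, Mt1, C3, Ms4a7 and Pld3 missed the threshold without WT replicate 2, with adjusted p from 0.0893 (Gins2) to 0.196 (C3), and without KO replicate 2 or 3. All but Il2rb, Jund and Mt1 also missed it without WT replicate 1 (from 0.0692, Nfatc1, to 0.197, Isg15). Without KO replicate 1 Gins2 (0.0609), Tacc3 (0.0601), Gmnn (0.0601), Il2rb (0.0531), Isg15 (0.0531), C3 (0.0778), Ms4a7 (0.0536) and Pld3 (0.0620) missed it, as did Pld3 without WT replicate 3 (0.0831) and Tacc3 without KO replicate 4 (0.0570). Mcm2 passed without WT replicate 3 (0.0425) or KO replicate 4 (0.0447), Mcm7 likewise (0.0414 and 0.0447), Pcna without WT replicate 3 (0.0346) and C1qb without KO replicate 4 (0.0255). DESeq2 called 134 genes, 67 higher and 67 lower, and the authors' deposited table lists 103. The count was 0 in a fit of these 2 groups alone, 68 with the GC offset (48 higher and 20 lower) and 1 after all Rorc-GFP+ libraries were thinned to 131327 counts. Whether the KO difference in Rorc-GFP+ cells exceeded that in proliferating cells was tested as a difference, with 0 genes called by edgeR (612 with an unadjusted p under 0.05, and 2 with DESeq2). The count was 1 without WT proliferating replicate 1 and 1 without KO Rorc-GFP+ replicate 4. The difference for Gins2 was −2.11 (adjusted p = 0.650), for Jund −1.27 (adjusted p = 0.560) and for Ms4a7 1.07 (adjusted p = 0.560).

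Among WT OTII cells, proliferating cells differed from nonproliferating ones in 3 genes, all higher. These were Cxcr3, a chemokine receptor of Th1 cells (61.5 ± 4.03 against 10.9 ± 5.54 CPM, log2 fold change 2.39, SE 0.39, adjusted p = 0.00740), the ATP-gated channel P2rx7 (1.90, SE 0.33, adjusted p = 0.0108) and the integrin Itgb1 (1.62, SE 0.30, adjusted p = 0.0203). Th1 program genes were higher in 1 of 14 cases (adjusted p = 0.00361, estimated 0.0620). Naive T cell genes had a median of −0.29 (1 of 15 lower when adjusted over the list alone, adjusted p = 0.00345), with Il7r at 19.6 ± 2.61 against 64.9 ± 18.4 CPM (−1.67, adjusted p = 0.999) and Igfbp4 at −1.03. Cell cycle genes had a median of 0.36 (adjusted p = 0.0152, estimated 0.582). Rorc was at −1.72, Tbx21 at −0.12 and Ifng, with no count in nonproliferating cells, at least 8-fold higher (all adjusted p = 0.999). Fold changes rose with transcript GC (r = 0.44), which the list tests did not adjust for. The count of 3 was 1 without proliferating replicate 2 or nonproliferating replicate 3, and 0 without nonproliferating replicate 1 or 2. Cxcr3 missed the threshold without nonproliferating replicate 1 (2.15, adjusted p = 0.0807) or 2 (2.47, 0.129). P2rx7 missed it without proliferating replicate 2 (0.309) or nonproliferating replicate 1 (0.0807), 2 (0.283) or 3 (0.0734). Itgb1 missed it without proliferating replicate 2 (0.521) or 3 (0.286) or nonproliferating replicate 1 (0.110), 2 (0.763) or 3 (0.0734). Cxcr3 lies on chromosome X from 101731535 to 101734269.

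WT Rorc-GFP+ OTII cells differed from WT proliferating cells in 151 genes, 146 higher and 5 lower. Rorc was higher (29.9 ± 9.75 against 5.36 ± 5.25 CPM, log2 fold change 2.58, SE 0.61, adjusted p = 0.0165), as were the abundant complement genes of macrophages. C1qa, C1qb and C1qc, the chains of complement C1q, were higher by 1.55 (2530 ± 261 against 865 ± 49.8 CPM, SE 0.27, adjusted p = 0.00144), 1.46 (adjusted p = 0.00235) and 1.60 (adjusted p = 0.000988). Monocyte and macrophage markers were higher in 8 of 16 cases (10 higher and 1 lower when adjusted over the list alone, median 1.29, adjusted p = 2.06e-13), and summed to 10400 ± 1100 against 4100 ± 410 CPM. DC markers were higher in 2 of 7 cases (all 7 when adjusted over the list alone, adjusted p = 2.00e-07, estimated 0.0868). Cell cycle genes had a median of 0.81 with none of 27 called (adjusted p = 2.24e-07, estimated 0.347), such as Rrm2 at 1.10 (adjusted p = 0.129). Ebi3 (1.87, adjusted p = 0.00918), Cd68 (1.32, adjusted p = 0.00240) and the phospholipid enzyme Lpcat2 (2.41, adjusted p = 0.00995) were higher, and Maf, a regulator of Th17 cells, was at 0.48 (adjusted p = 0.649). Tbx21 was at 0.13 (adjusted p = 0.972) and Ifng at −3.01 (adjusted p = 0.677). Rorc missed the threshold without proliferating replicate 1 (2.10, adjusted p = 0.0801) or 2 (2.87, adjusted p = 0.136) or Rorc-GFP+ replicate 1 (2.39, adjusted p = 0.0634). Cd68 and Ebi3 missed it without proliferating replicate 2 (adjusted p = 0.0555 and 0.150) and Lpcat2 without proliferating replicate 1 (adjusted p = 0.0676). The count of 151 was 35 without proliferating replicate 2, 296 with DESeq2 and 43 after thinning to one depth, where Rorc was at 2.95 (adjusted p = 0.206), Ebi3 at 1.99 (adjusted p = 0.0982) and Lpcat2 at 2.35 (adjusted p = 0.233). Rorc lies on chromosome 3 from 94372794 to 94398276 and C1qa on chromosome 4 from 136895917 to 136898803.

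**Figure D4:**
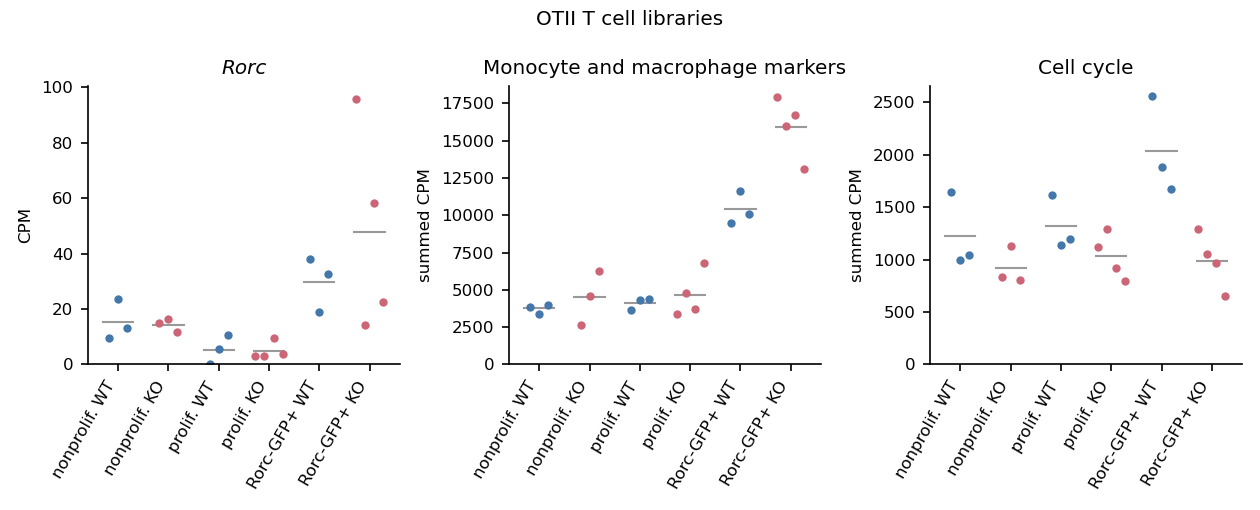
Rorc CPM (left) and summed CPM of macrophage markers (middle) and cell cycle genes (right) in the 6 groups of OTII cells; points are libraries (blue WT, red KO, n = 3 or 4) and grey lines group means. Macrophage markers averaged 10400 CPM in WT and 15900 in KO Rorc-GFP+ cells, against 4100 in WT proliferating and 3750 in WT nonproliferating cells.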

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

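All counts of splits, and the tests of the T cell list against dilution, of the CD3 complex, of gamma-delta T cell genes and of the ratio of cell cycle to T lineage sums, were chosen only after the results they concern had been seen. The shuffle of population labels was added after the shuffle of conditions.

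Single libraries lay far from the others of their group in 3 of 45 tested values, and chance marks about 1 in 20 groups. In KO proliferating OTII cells replicate 3 had 125 CPM of Irf4 (the others 52 to 55.6) and 9.59 CPM of Rorc (the others 3.09 to 3.59). In KO Rorc-GFP+ cells replicate 2 had 14.1 CPM of Ifng, against 0 in the others.

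The change after Candida albicans differed between populations by a test of the difference itself, which does not separate a response from a changed mix of cells in a sort. Between Aire-GFP+ and MHCII+ ILC3, 285 genes differed, including Aire (−3.14), Il7r (1.25), H2-DMb1 (−1.48), H2-DMb2 (−1.87), Ccl2 (4.34), Ccl7 (4.53), Gzma (5.93), Nkg7 (2.47), Cd3d (2.95), Cd3g (2.8), Col1a2 (4.67), Dcn (3.2), Iglon5 (−4.53), Lingo1 (−3.51) and Fabp6 (−4.23). Without each of 9 of the 12 libraries in turn Il7r missed the threshold in this difference (adjusted p from 0.0514 to 0.181).

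Between Aire-GFP+ ILC3 and ILC3, 336 genes differed by the same test, including H2-Aa (−1.83), Il7r (1.8), Cd74 (−1.93), Cxcr6 (2.8), Ccl2 (3.3), Ccl4 (1.83), Ccl7 (3.58), Col1a2 (4.33), Jund (−1.83), Pfkl (−1.73) and Slpi (−3.94).

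Between Aire-GFP+ ILC3 and DC, 1135 genes differed by that test, including Rorc (2.84), Marcksl1 (−2.4), Cd63 (−1.75), Il15ra (−2.02), Tmem123 (−1.77), Ccl4 (2.67), Ccl7 (5.72), Ccl2 (4.14), Dcn (5.74), Cxcr6 (4.76), Nfkb1 (−1.28), Cd40 (−1.1) and Cd1d1 (−3.76).

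Fold changes of stimulated Aire-GFP+ ILC3 fell with transcript GC content (r = −0.43 over 4434 genes, median GC 43% in genes called higher and 56.9% in genes called lower). The shallow libraries alone do not account for it, since r was −0.34 without them. With a GC offset 38.4% of the called genes stayed called in the same direction, which leaves open how many calls stem from a GC trend between libraries. The offset moved B2m from 0.65 (SE 0.18) to 0.09 (SE 0.17, adjusted p = 0.853), Il7r from 1.22 (SE 0.26) to 0.69 (adjusted p = 0.0627) and Il6 from 1.80 (SE 0.40) to 1.22 (SE 0.39, adjusted p = 0.0898). A real response that favours transcripts of low GC would look the same, and DC had r = −0.40.

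Stimulated MHCII+ ILC3 had more transcripts of Aire-GFP+ ILC3 and fewer of the CD3 complex. Of 144 markers, 76.4% moved towards stimulated Aire-GFP+ ILC3, as a larger share of such cells or a rise of Aire within cells would give. The rest, such as Ccl22 and Il12b, moved away, so no single share (median 15.8%, quartiles 2.16% and 31.4%) covers all. The T cell list lay −0.41 beyond the −0.25 of dilution by the median share, which a larger share could cover. Cd3d, Cd3e, Cd3g and Cd247 lay −2.54 beyond the dilution, but as the list's 4 called lower they decide nothing on it. Fewer gamma-delta T cells, whose CD3 is a target of the stated depletion, remain open. Of their 7 genes 4 were called lower and none higher (median −2.6, some picked for their fall), and the 4 not named before had −0.69 with 1 called.

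Macrophage transcripts were higher in Rorc-GFP+ OTII libraries, and cell cycle transcripts were lower in the KO ones. A further 16 macrophage transcripts had a median of 1.39 in WT Rorc-GFP+ against proliferating cells, all above 0, as macrophages or their RNA in the sort would give. Dilution by such RNA lowers both lists alike, so it does not account for the whole fall of the cell cycle list, whose log2 ratio to the T lineage sum differed by −0.79 (−1.5 ± 0.5 in WT, n = 3, −2.29 ± 0.43 in KO, n = 4, exact permutation p = 0.0286). Low depth does not account for the cell cycle list, whose median was −0.94 after thinning to 131327 counts. Fewer dividing cells and less division remain open, untested, as does dilution for the 23 genes called lower, since T lineage genes lay 1.16 above them but those genes were chosen for being lower.

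Other splits of the libraries were called in the same way. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and the real one alone called as many genes in 10 comparisons. Real and highest other counts were 696 and 51 for stimulated Aire-GFP+ ILC3, 1442 and 0 for MHCII+ ILC3, 16 and 5 for ILC3, and 3710 and 1 for DC. They were 5539 and 0 for Aire-GFP+ ILC3 against ILC3, 4357 and 101 against MHCII+ ILC3, 5607 and 6 against DC, and 4303 and 0 for MHCII+ ILC3 against ILC3. For WT OTII cells they were 3 and 0 for proliferating against nonproliferating and 151 and 1 for Rorc-GFP+ against proliferating cells.

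A real count of 0 is matched by any split, so its splits say nothing about chance. It was 0 in Aire KO against WT cells (10 of 10 splits), where 1 other split called 159 genes, which points to structure among the samples other than the genotype. KO nonproliferating cells had 0 (10 of 10 splits, highest 0) and KO proliferating cells 0 (35 of 35, highest 10). For KO Rorc-GFP+ cells 2 of 35 splits, the real one included, called at least the real 33, and the other of them called 154, which again points to structure among the samples.

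For the differences between responses, 40 splits were drawn by shuffling conditions within populations or populations within conditions. At least the real 285 of Aire-GFP+ against MHCII+ ILC3 came in 6 and 8 of 40 (highest 1984 and 4990), the real 336 against ILC3 in 2 and 6 (544 and 6203), and the real 1135 against DC in 4 and 5 (1593 and 4113). For the KO difference between Rorc-GFP+ and proliferating cells, with a real 0, the match of 40 and 40 is fixed as well (highest 390 and 444). Shuffles of these kinds mix real group differences into the splits, and their high counts point to that structure.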

How the results depend on the processing

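Of the single-gene results none reversed under any alternative. DESeq2 size factors left 437 the same, 1 stronger and 2 weaker, the DESeq2 test 420, 13 and 7, no filter 431, 5 and 4, the fit of only the groups compared 364, 6 and 36, and the GC offset 417, 3 and 20. Leaving out both shallow libraries left 181 the same and 16 weaker, the replicate block 181 and 11, thinning 22 and 24, and single libraries left out 2771 the same, 16 stronger and 231 weaker. Of the list results 333 stayed and 95 were weaker with an estimated correlation.

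Numbers of genes called moved by more than 1.5 times as follows, and the cause was not tested. With the DESeq2 test they were 34 in stimulated ILC3, 16 in Aire KO, 2 in KO proliferating, 134 in KO Rorc-GFP+, 296 in Rorc-GFP+ against proliferating cells and 2 in the KO difference. In a fit of only the groups compared they were 228 in Aire-GFP+ ILC3, 10 in ILC3, 189 and 142 for the differences of Aire-GFP+ ILC3 from MHCII+ ILC3 and ILC3, 1 in KO proliferating and 0 in KO Rorc-GFP+ cells. The GC offset gave 336 in Aire-GFP+ ILC3, 149 for its difference from ILC3 and 68 in KO Rorc-GFP+ cells. Without both shallow libraries the first 2 were 333 and 209. Thinning, which leaves fewer counts, gave 1 in KO Rorc-GFP+ and 43 in Rorc-GFP+ against proliferating cells.

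With the replicate number as a block, KO proliferating cells had 1 and KO Rorc-GFP+ cells 11 genes, against 0 and 33, and 7 of the 11 were among the 33. Whether the numbers pair the libraries is not settled. Correlations between same-numbered libraries ran from −0.32 to 0.62, and in no comparison were all over 0.1. In ILC3 with and without Candida they ran from 0.069 to 0.34, and 3 of 3 libraries correlated best with their own number. Between KO and WT proliferating OTII cells 0 of 3 did.

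With each library left out in turn the counts ran from 190 to 1216 in stimulated Aire-GFP+ ILC3, 642 to 1636 in MHCII+ ILC3, 5 to 108 in ILC3 and 2787 to 3114 in DC. For differences of Aire-GFP+ ILC3 they ran from 178 to 342 (MHCII+ ILC3), 106 to 690 (ILC3) and 727 to 1427 (DC). They ran from 0 to 8 in Aire KO, 0 to 165 in KO Rorc-GFP+, 0 to 3 in proliferating against nonproliferating, 35 to 128 in Rorc-GFP+ against proliferating cells and 0 to 1 in the KO difference. Where a group keeps few libraries, the fit takes its spread from the other groups.

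The share of called genes that were higher moved from 49.6% to 38.7% in MHCII+ ILC3 against ILC3 and from 30.3% to 70.6% in KO Rorc-GFP+ cells with the GC offset. It moved from 50.6% to 61.1% in DC without a filter and from 31.2% to 76.5% in stimulated ILC3 with the DESeq2 test.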

Other observations

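Among cytokine genes, Il12b was higher in MHCII+ ILC3 than in ILC3 (5.63, adjusted p = 8.37e-14, 89.7 ± 3.11 against 1.79 ± 0.879 CPM) and so was Ebi3 (3.23, adjusted p = 1.12e-12), while Il6 was lower (46.2 ± 14.3 against 392 ± 19.2 CPM, adjusted p = 3.17e-08). Stromal markers were lower too (489 ± 133 against 5070 ± 247 CPM), and no test addressed a stromal source of Il6, Ccl2 or Ccl7. Iigp1 was lower as well (−3.06, adjusted p = 6.97e-10). After Candida albicans Cck rose in MHCII+ ILC3 (2.81, adjusted p = 0.00252), as did Tmprss11d (2.56, adjusted p = 2.68e-05).

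Genes beside Aire on chromosome 10 prompted a hypothesis of shared regulation, with all tests chosen after the values were seen. Around Aire (8.58), 6 tested genes in a row were called higher in Aire-GFP+ ILC3 than in ILC3 (Sumo3 1.10, Ube2g2 0.67, Pfkl 2.84, Dnmt3l 6.37, Icosl 5.79). Of 1000 shuffled gene orders 80.9% held a run as long and as high somewhere, and the real order held 12, deciding nothing about a run at Aire. In MHCII+ ILC3, where Aire rose by 2.64 after stimulation, the median of its neighbours was −0.03, with none called higher and Pfkl lower (−0.90). Dnmt3l was at 1.98 there (adjusted p = 0.0501), and passed with DESeq2 size factors (0.0484), no filter (0.0479) or the GC offset (0.0365). In Aire-GFP+ ILC3 all were negative, as was Aire (−0.50). Neither separates Aire from stimulation, so shared regulation stays open.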
